A study of Homo sapiens with 2 samples.

How the data were processed

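Total RNA from MDA-MB-231 cells and from RT-R-MDA-MB-231 cells was sequenced with a Lexogen QuantSeq 3' tag kit, 1 library per line, per the labels' protocols. Both lines were grown in the same medium with 10% serum, and the resistant line had received X-ray fractions of 2 Gy to a total of 50 Gy. The authors deposited raw whole-number counts per gene symbol for each library, with no normalization. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Bowtie2, bedtools and the hg19 build were used. The role and settings of each tool, the gene annotation, the use of strand and the handling of reads that match several places are not given in the sources used here. Reads of close paralogs and of overlapping or antisense genes therefore cannot be told apart with certainty, and such genes are marked as uncertain where named. A 3' tag protocol counts transcript ends, so gene length has little weight in the counts, but a gene whose end is annotated wrongly can be missed. No molecular identifiers are mentioned, so counts are of reads and not of molecules.

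Each deposited count table had 25737 rows in the same order and no row without a gene name. Rows with the same symbol were summed to give 24462 symbols. There were 286 repeated symbols, of which 22 had counts on more than 1 row, and 6071 symbols had no count in either library. The totals were 9255008 counts for the parental and 10014804 for the RT-R library. Across 12644 genes with at least 20 counts in a library, the Pearson correlation of log2(count + 1) was 0.937, a value across genes, which are not independent replicates.

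Library sizes were scaled by the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, giving an RT-R to parental size ratio of 1.12 against 1.08 for the totals. Log2 ratios of RT-R to parental were taken from scaled counts plus a pseudocount of 0.5. Fold ratios carry an exact conditional (Clopper-Pearson) 95% interval, computed with scipy 1.17.1 in Python 3.11.15, which covers counting error only. A gene was called higher or lower when it had at least 20 counts in a library, a ratio of at least 2-fold and an interval on one side of 1. A count of 0 was set at 3 counts in that library for a bound on a ratio. Such a bound takes the count of the other library as exact, so it is less strict than the lower end of the intervals. No ratio was given when both libraries lay at or under 3. No test across samples is possible with 1 library per group, so no p-values were computed, and edgeR was used for scaling alone. The number of calls from counting error was estimated from 100 simulated library pairs with equal expression.

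For 40 gene lists fixed before the data were examined, the median log2 ratio of members passing the count minimum was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5. The percentile describes these libraries and is not a test across cultures. The genes named are the 15 highest and 15 lowest, ranked by the interval bound nearest to 1 and leaving out genes without a proper symbol, the genes of the series title, and up to 2 highest and 2 lowest members per list by the same ranking. A gene named outside this rule is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

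Chromosome and gene order came from the RefSeq gene table of assembly GRCh38.p14, matched by symbol or by an unambiguous synonym, which placed 98.6% of the genes measured. Because the counts were made on hg19, no coordinates are printed. Windows held about 30 neighbouring genes with at least 50 counts over both libraries. A gene's neighbours were the 15 measured genes on each side. Transcript GC content over the last 300 bases and transcript length came from GENCODE v29 transcripts and were found for 97.8% of the genes.

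The calculations were tested on simulated libraries of the RT-R against parental comparison before use. With 200 of 12435 measured genes changed, calls recovered 0 of 50 genes changed 1.5-fold, 25 of 50 changed 2-fold, 48 of 50 changed 3-fold and 50 of 50 changed 4-fold, none in the wrong direction, with 35 unchanged genes called. Of 200 random lists of 25 genes, 3% stood apart, and 100% did so when shifted by 0.3 on the log2 scale. With X-linked genes simulated lower by a log2 ratio of -0.8, all 13 windows on the X and 0 of 379 others passed 0.4. Apart from the changes put in, these simulations held counting error only. Counting error alone gives a median absolute log2 ratio of 0.08, against 0.34 in the data. The rates therefore do not carry over to the wider spread of the data or to lists of genes that vary together.

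The alternatives tried were scaling by total counts, by the median of ratios (DESeq2 1.42.0) and by the upper quartile, a pseudocount of 5, count minimums of 0 and 100, thresholds of 1.5-fold and 4-fold, fold alone, the mean of each list, 20 expression bins, and each list without its most changed member. Subtraction of chromosomal neighbours, removal of X-linked genes and removal of genes whose counts were identical to those of an overlapping gene were added after seeing the data. Mitochondrially encoded transcripts were not analysed here.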

Results

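The data describe messenger RNA levels in 2 human cell lines. MDA-MB-231 is an established triple negative breast cancer line, that is, one lacking the estrogen receptor, the progesterone receptor and HER2 amplification. RT-R-MDA-MB-231 is its radiotherapy-resistant derivative, made by repeated X-ray fractions of 2 Gy up to a total of 50 Gy. Each line was represented by 1 library made from total RNA with a 3' tag sequencing kit, which reads mainly the ends of polyadenylated transcripts. The parental library held 9255008 counts over 16631 detected gene symbols, and the RT-R library held 10014804 counts over 17598 symbols. The 10 most abundant genes took 6.05% of the parental counts and 5.53% of the RT-R counts. With 1 library per line, no difference given here has a replicate check and no p-value can be given. The intervals are 95% intervals for counting error within these libraries only. They do not cover variation between cultures, and reads amplified by PCR are not independent molecules.

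The comparison of RT-R with parental cells asks how expression in the irradiated derivative differs from that in the line it came from. The RT-R cells expressed far more MMP1, the interstitial collagenase, with 8 counts in the parental library against 2064 in RT-R, a 231-fold ratio (117 to 537). They also expressed more FN1, the matrix protein fibronectin, which went from 6484 to 26555 counts and rose 3.67-fold (3.57 to 3.77). S100A4, a calcium-binding protein associated with cell motility, went the other way, from 31964 to 4122 counts, 8.65-fold lower (8.37 to 8.94). Of 12644 genes with at least 20 counts in a library, 871 (6.89%) rose at least 2-fold and 502 (3.97%) fell at least 2-fold with an interval on one side of equal expression. At least 4-fold differences were found for 292 higher and 67 lower genes, and at least 10-fold differences for 108 higher and 12 lower genes. Counting error alone, simulated in 100 pairs of libraries with equal expression, gave a mean of 18.9 higher and 15.8 lower genes, and at most 32 and 27. The median absolute log2 ratio was 0.34, against 0.08 from counting error alone. Without the interval rule, 14.9% of the measured genes were at least 1.5-fold higher and 12.6% at least 1.5-fold lower. The 1.5-fold counts of the gene lists below are to be read against these shares. Genes were also ranked by their mean log2 scaled count over both libraries into 5 equal groups. Of the 871 higher genes, 560 lay in the lowest group, where the median gene had 67 counts over both libraries, and 49 lay in the highest. Of the 502 lower genes, 232 lay in the lowest group and 41 in the highest. A gene near 0 counts in 1 library has a low mean by construction, even when the other library holds many counts.

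**Figure D1:**
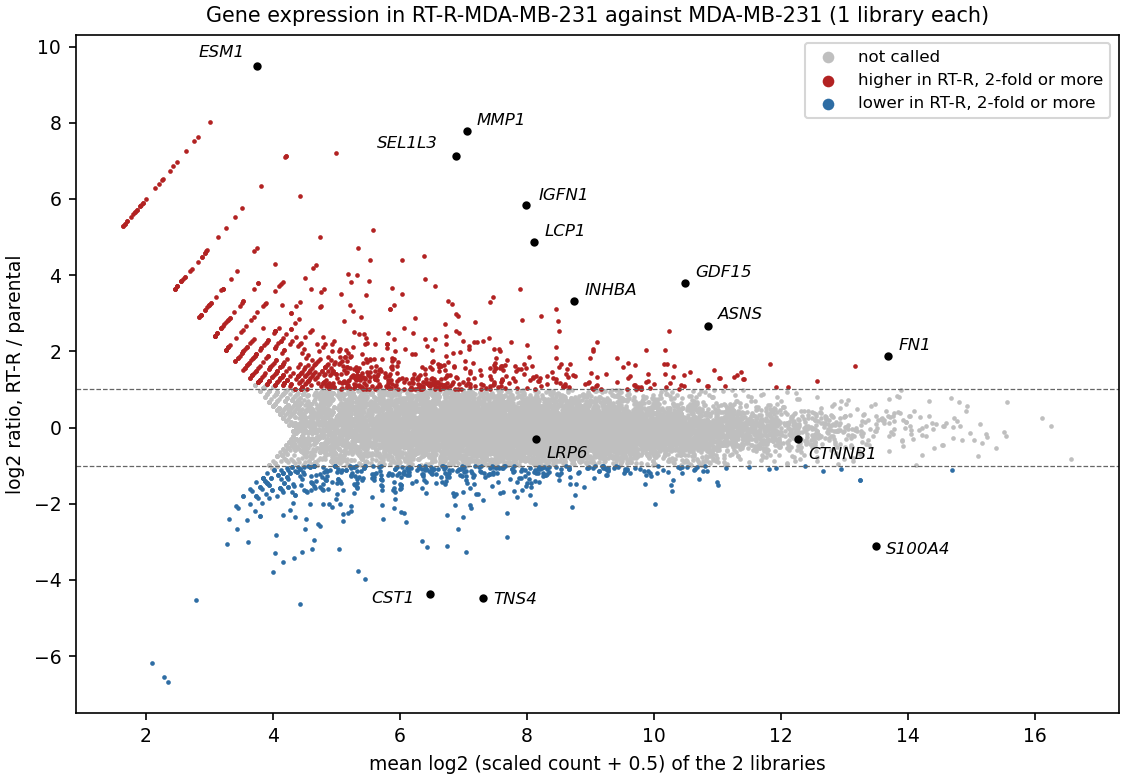
Log2 expression ratio of RT-R to parental cells (y axis) against mean log2 scaled count of the 2 libraries (x axis), 1 point per gene among 12644 genes, with dashed lines at 2-fold. Red points are the 871 higher genes and blue points the 502 lower ones, with genes named in the plot in black; MMP1, SEL1L3, IGFN1 and LCP1 lie far above the cloud and S100A4 far below it, while LRP6 and CTNNB1 lie between the dashed lines.

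Among the 15 genes highest in RT-R were several that the parental library barely contained. ESM1, which encodes the secreted proteoglycan endocan, had 0 parental counts and 382 RT-R counts, so it was at least 114-fold higher when the parental level is set at the 3 counts that a count of 0 allows. PHGDH, the first enzyme of serine synthesis, had 1 parental count and 228 RT-R counts, a 204-fold ratio with an interval from 36.3 to 8109.7. THBS2, the matrix glycoprotein thrombospondin 2, had 2 and 187 counts, a ratio of 83.8 (22.9 to 697). The cancer-testis gene MAGEB2 had 2 and 405 counts, a ratio of 182 (49.9 to 1504). LCP1, the actin-bundling protein L-plastin, rose from 48 to 1586 counts, 29.6-fold (22.2 to 40.4). IGFN1 rose 58.7-fold (41.2 to 86.6), SEL1L3 147-fold (77.4 to 323), and NFATC4, a calcineurin-dependent transcription factor, 38.7-fold (18.5 to 97.0). CACNA2D4, a calcium channel subunit, had 1 and 133 counts, a ratio of 119 (21.0 to 4745). The other 5 had no parental count. They were the kinase gene ALPK2 (at least 40.9-fold higher), the phospholipase C genes PLCB4 (at least 31.1-fold) and PLCH2 (at least 28.7-fold), the Wnt ligand gene WNT5A (at least 24.2-fold) and the glycosyltransferase gene GALNT9 (at least 19.7-fold).

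The 15 genes lowest in RT-R included adhesion, secreted and epithelial genes. TNS4, a focal adhesion protein of the tensin family, fell from 708 to 35 counts, 22.6-fold (16.1 to 32.7). The secreted cystatins CST1, CST2 and CST4, inhibitors of cysteine proteases, were 21.2-fold (13.6 to 35.2), 14.2-fold (7.69 to 29.1) and 9.78-fold (7.15 to 13.7) lower. These genes are close copies of one another on chromosome 20, so how reads were divided among them is uncertain. DMBT1, a secreted scavenger receptor protein, fell from 101 to 4 counts, 28.2-fold (10.7 to 105), and the estrogen-responsive gene TFF1 from 34 to 0, at least 12.6-fold. The chemerin receptor gene CMKLR1 was 8.66-fold lower (6.16 to 12.5), NTM 16.5-fold (8.996 to 33.8) and TMEM163 15.6-fold (5.77 to 59.3). The noncoding gene LINC00960 had 31 counts and 1 count, a ratio of 34.6 (5.76 to 1409). The remaining 3 genes lie on the X chromosome, where the median of 424 measured genes was itself 1.72-fold lower in RT-R. These were PAGE5 (48 and 0 counts, at least 17.8-fold lower), the calcium-binding protein gene RGN (44 and 0 counts, at least 16.4-fold) and FAM133A (8.96-fold, 6.12 to 13.6). S100A4 overlaps S100A5 in the reference gene table, but S100A5 had only 49 and 10 counts.

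The genes at the centre of the series title were next compared, since the study concerns sterol efflux by ABCG8 and signalling through LRP6, Wnt and beta-catenin in the resistant cells. ABCG8, a sterol transporter that works as a pair with ABCG5, had 0 counts in the parental and 2 in the RT-R library. ABCG5 had 0 and 1. Both libraries lay at or under 3 counts for both genes, so a difference in either was not detectable at this depth and no ratio is given. ABCG5 overlaps DYNC2LI1 in the reference gene table, which had 40 and 51 counts. LRP6, a Wnt co-receptor, had 296 parental and 269 RT-R counts, a log2 ratio of -0.29 and 1.23-fold lower (1.04 to 1.45). Its relative LRP5 was 1.39-fold lower (1.26 to 1.55). CTNNB1, which encodes beta-catenin, had 5158 and 4703 counts and was 1.22-fold lower (1.18 to 1.27). All 3 intervals, which cover counting error only, excluded equal expression, and none of the 3 genes reached 2-fold. The median absolute log2 ratio over all measured genes was 0.34. LRP6 (-0.29) and CTNNB1 (-0.29) differed by less than this, and LRP5 (-0.48) by more. After the median of its chromosomal neighbours was subtracted, the log2 ratio of CTNNB1 was -0.0028, that of LRP6 -0.12 and that of LRP5 -0.50. The median of the 3 measured genes lay at percentile 20.1 of random lists matched on expression.

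Genes of sterol export and storage moved in both directions. ABCG1, a cholesterol exporter, fell from 69 to 8 counts, 9.62-fold (4.62 to 23.2), and ABCA1, another cholesterol exporter, fell from 406 to 213, 2.13-fold (1.80 to 2.52). APOE, the lipid carrier apolipoprotein E, rose from 6 to 29 counts, 4.33-fold (1.77 to 12.8), and the sterol-binding protein gene OSBP had a ratio of 1.68 (1.45 to 1.95), below the 2-fold limit. Of the 17 measured genes of the sterol efflux and LXR target list, 3 were at least 1.5-fold higher and 3 at least 1.5-fold lower, with a median log2 ratio of -0.12 at percentile 22.7. These counts lay close to the shares over all measured genes, 14.9% higher and 12.6% lower. In cholesterol synthesis and uptake, 4 of 25 genes were at least 1.5-fold higher and 3 lower, with a median of 0.13 at percentile 96.0, just inside the range of random lists. The synthesis enzyme gene HMGCS1 had a ratio of 1.66 (1.52 to 1.81), below the 2-fold limit. NSDHL fell 2.00-fold (1.78 to 2.26) and EBP was 1.96-fold lower (1.83 to 2.10), and both of these synthesis genes lie on the X chromosome. With each gene set against its chromosomal neighbours, the median of this list was 0.17, at percentile 98.2. The fatty acid synthesis list had 0 of 20 genes at least 1.5-fold higher and 2 lower, with a median of -0.18 at percentile 14.5.

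Wnt pathway genes showed single large differences rather than a common shift. Of 31 measured receptors and other components of the pathway, 2 rose and 0 were 1.5-fold lower: WNT5A, given above, and the transcription factor gene TCF7L1 (14 and 42 counts, 2.69-fold, 1.44 to 5.33). The median log2 ratio of this list was 0.05, at percentile 78.4. Among 16 Wnt/beta-catenin target genes, 3 were at least 1.5-fold higher and 3 lower, and the median was 0.19 at percentile 92.5. Their mean was 0.061 at percentile 55.7, and their median after subtraction of chromosomal neighbours was 0.015 at percentile 52.95. LEF1, a transcription factor that partners beta-catenin, rose 2.03-fold (1.30 to 3.24) from 30 to 68 counts, and its relative TCF7 had a ratio of 1.62 (1.18 to 2.25). BMP4 was 1.80-fold lower (1.69 to 1.92) and BIRC5, which encodes survivin, 1.71-fold lower (1.60 to 1.83), both short of the 2-fold limit. The drug and phospholipid ABC transporters had a median of -0.10 at percentile 32.1, with 1 of 15 at least 1.5-fold higher.

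**Figure D2:**
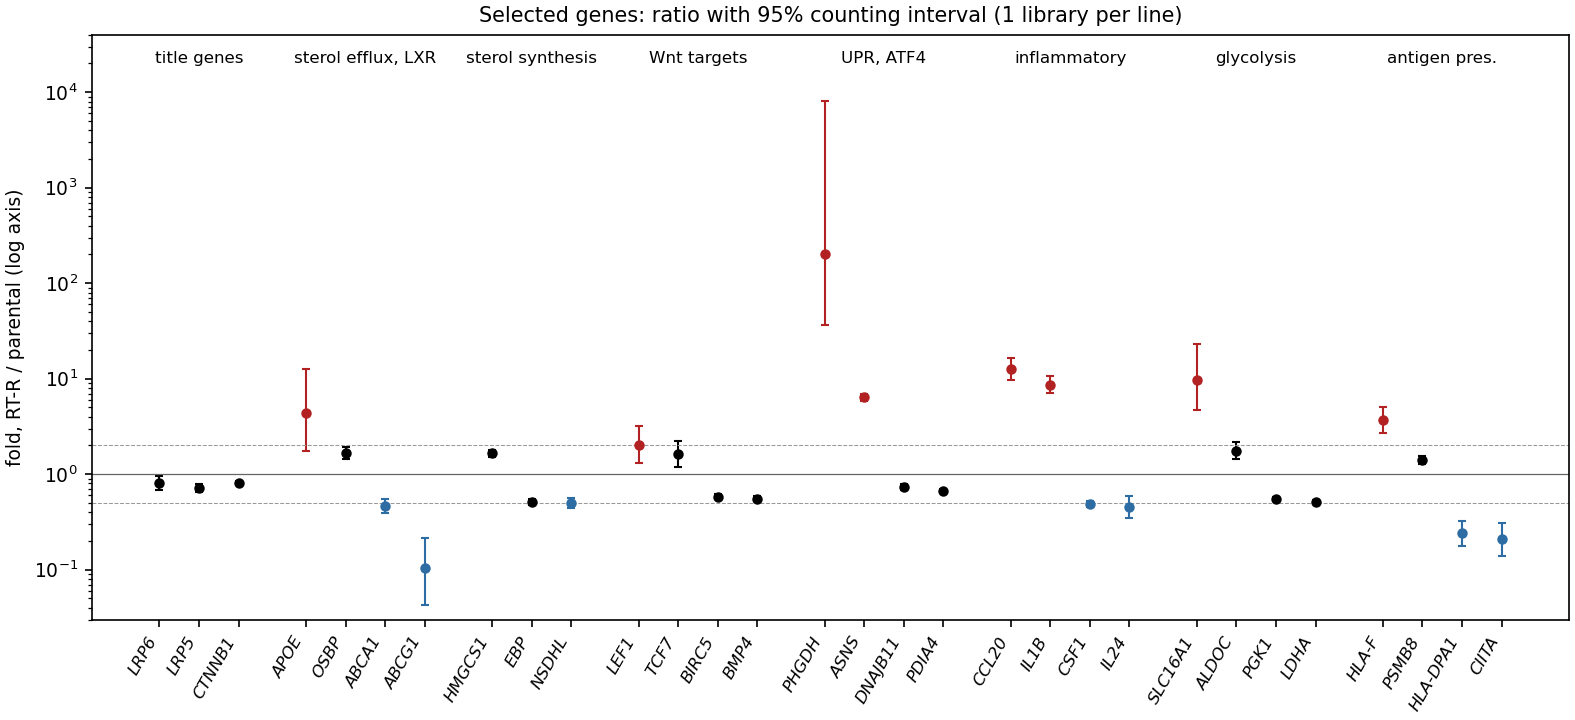
Ratio of RT-R to parental expression (log y axis) for selected genes of the series title and of 7 gene lists, with bars giving the 95% counting interval from 1 library per line and dashed lines at 2-fold. Red and blue mark genes called higher and lower; LRP6, LRP5 and CTNNB1 lie just below equal expression, ABCG1 is 9.62-fold lower, and PHGDH, resting on 1 parental count, has an interval from 36.3 to 8109.7.

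The clearest group change was in the list that joins targets of the transcription factor ATF4 with genes of the unfolded protein response. Of 25 measured members, 15 were at least 1.5-fold higher, 10 of them past the 2-fold rule, and 0 were 1.5-fold lower. Its median log2 ratio was 0.77, above all 10000 random lists. In a split made after the values were seen, the 11 ATF4 targets had a median of 2.03, all at least 1.5-fold higher. The 14 endoplasmic reticulum members had a median of 0.17, with 4 at least 1.5-fold higher. ASNS, asparagine synthetase, rose from 686 to 4897 counts, 6.40-fold (5.91 to 6.94), next to PHGDH given above. SESN2, a stress-induced regulator of mTORC1, rose 4.06-fold (3.54 to 4.68), and SLC7A11, the cystine transporter, rose 4.09-fold (3.69 to 4.55). The endoplasmic reticulum proteins PDIA4 and DNAJB11 had the lowest values, 1.496-fold (1.41 to 1.58) and 1.35-fold (1.26 to 1.46) lower. In the NRF2 antioxidant list, 6 of 23 genes were at least 1.5-fold higher and 1 lower, with a median of 0.08 at percentile 82.4 but a mean of 0.47 at percentile 99.4. After subtraction of chromosomal neighbours the NRF2 median was -0.059. AKR1C3, which has close copies, rose 5.71-fold (3.62 to 9.40). The p53 target list had 7 of 24 genes at least 1.5-fold higher and 2 lower, with a median of 0.17 at percentile 96.0 and a mean of 0.42 at percentile 99.4, outside the random range. Its top gene GDF15, a stress-induced secreted factor, rose 13.9-fold (12.5 to 15.5), whereas the apoptosis effector BAX was 1.61-fold lower (1.48 to 1.75). Heat shock genes lay lower, with 0 of 16 at least 1.5-fold higher and 4 lower and a median of -0.32 at percentile 1.93. HSPB1 fell 2.21-fold (2.07 to 2.36). That list was within the random range by its mean, -0.24, or without its most changed member, -0.31.

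Inflammatory secreted factors rose as a group. Of 25 measured genes in the NF-kB list, 10 were at least 1.5-fold higher, 9 of them past the 2-fold rule, and 4 were lower, with a median log2 ratio of 0.38 at percentile 99.98. The chemokine CCL20 rose from 63 to 883 counts, 12.6-fold (9.73 to 16.5), and the cytokine IL1B from 112 to 1083, 8.67-fold (7.13 to 10.6). CSF1 and IL24 went against the group and fell 2.06-fold (1.92 to 2.22) and 2.204-fold (1.69 to 2.90). Interferon-stimulated genes were split, with 7 of 27 at least 1.5-fold higher and 6 lower and a median of -0.03 at percentile 43.7. MX1 rose 2.03-fold (1.44 to 2.89), while IFIT1 fell 2.71-fold (2.18 to 3.38) and ISG15 2.03-fold (1.88 to 2.202). In antigen presentation, 7 of 24 genes were at least 1.5-fold lower and 1 higher, with a median of -0.24 at percentile 2.94, just inside the random range. The mean of this list was -0.37 at percentile 0.13, outside it, and the median after subtraction of chromosomal neighbours was -0.062 at percentile 31.5. Several members lie close together on chromosome 6 and serve as one another's neighbours, so the subtraction can remove part of their own shift. CIITA, the master regulator of MHC class II genes, fell from 137 to 32 counts, 4.77-fold (3.23 to 7.25), and the class II gene HLA-DPA1 from 223 to 60, 4.15-fold (3.10 to 5.61). The class I gene HLA-F, which shares sequence with other HLA genes, rose 3.69-fold (2.71 to 5.10). Immediate early genes had a median of 0.34 at percentile 98.3, with 4 of 16 at least 1.5-fold higher and 1 lower, and the phosphatase gene DUSP1 rose 3.03-fold (2.22 to 4.196). Their mean, 0.41, and their median without the most changed member, 0.32, lay within the random range.

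Matrix and mesenchymal genes were higher in RT-R. Of 23 measured mesenchymal genes, 11 were at least 1.5-fold higher and 3 lower, with a median of 0.38 at percentile 99.9. COL6A2, a collagen VI chain, rose from 51 to 566 counts, 9.95-fold (7.46 to 13.5), as did FN1 given above, while S100A4 and the cadherin gene CDH11 (2.91-fold, 2.32 to 3.67) fell. Of 21 epithelial junction and keratin genes, 9 were at least 1.5-fold higher and 2 lower, with a median of 0.40 at percentile 99.9. The desmosomal gene DSP rose 2.47-fold (2.22 to 2.75) and the claudin gene CLDN7 2.01-fold (1.83 to 2.22), while CLDN4 fell 2.03-fold (1.88 to 2.196). The epithelial list no longer stood apart with a minimum of 100 counts (median -0.050, percentile 51.4) or by its mean (0.32, percentile 92.7). Collagens, laminins and integrins had 10 of 25 genes at least 1.5-fold higher and 1 lower, with a median of 0.29 at percentile 99.97. Stem-like state markers had 6 of 16 at least 1.5-fold higher and 1 lower, with a median of 0.45 at percentile 99.97. CD24, which has close copies, rose 2.86-fold (2.23 to 3.69) and the aldehyde dehydrogenase gene ALDH1A3 2.38-fold (1.98 to 2.87), whereas SOX9 was 1.56-fold lower (1.37 to 1.77). All members were counted alike, whether high or low expression marks the state, so the list median does not show a stem-like state.

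Genes of extracellular proteolysis also lay higher, with 5 of 20 at least 1.5-fold higher and 3 lower and a median of 0.24 at percentile 98.9. Beside MMP1, the protease inhibitor SERPINE2 rose 3.56-fold (3.10 to 4.10), while the metalloproteinase inhibitors TIMP1, on the X chromosome, and TIMP3 fell 2.30-fold (2.10 to 2.52) and 2.02-fold (1.89 to 2.17). In the TGF-beta response list, 9 of 25 genes were at least 1.5-fold higher and 2 lower, with a median of 0.25 at percentile 99.0. INHBA, the activin A subunit, rose from 127 to 1427 counts, 10.1-fold (8.40 to 12.2), and SMAD6 rose 2.94-fold (1.96 to 4.52). After subtraction of chromosomal neighbours the medians of these lists were 0.16 and 0.20, inside the random range. YAP/TEAD targets had a median of 0.10 at percentile 92.7, with 3 of 23 at least 1.5-fold higher and 1 lower, and 0.24 at percentile 99.7 after the same subtraction. Receptor tyrosine kinases and ligands had 7 of 22 genes at least 1.5-fold higher and 6 lower, with a median of 0.01 at percentile 63.1, and 0.31 at percentile 99.0 with no count minimum. The ligand gene PDGFA rose 2.52-fold (2.22 to 2.87) and AREG, which encodes amphiregulin, fell 3.57-fold (2.92 to 4.39).

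Proliferation and glycolysis genes were lower in RT-R by small amounts. The G1/S and DNA replication list had 9 of 30 genes at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.36 at percentile 0.090. RFC2, a subunit of the clamp loader, was 1.92-fold lower (1.65 to 2.22) and the transcription factor gene E2F1 1.78-fold lower (1.64 to 1.92). The G2/M and mitosis list had 6 of 32 genes at least 1.5-fold lower and 0 higher, with a median of -0.32 at percentile 0.080, and CDCA3 fell 2.28-fold (2.08 to 2.499). Glycolysis genes had the lowest median of all lists, -0.44 at percentile 0.030, with 5 of 21 genes at least 1.5-fold lower and 2 higher. LDHA, lactate dehydrogenase A, went from 10007 to 5776 counts and was 1.93-fold lower (1.87 to 2.00), short of the 2-fold limit. SLC16A1, the lactate transporter MCT1, rose from 8 to 86 counts, 9.64-fold (4.68 to 23.04), and the mean of the list, as opposed to its median, was -0.18, inside the random range. Hypoxia response genes moved both ways, with 4 of 25 at least 1.5-fold higher and 7 lower and a median of -0.11 at percentile 25.3, while their mean of -0.25 at percentile 1.59 lay outside the random range. ADM, which encodes adrenomedullin, rose 3.18-fold (2.91 to 3.48), while the carbonic anhydrase gene CA9 fell 8.92-fold (3.16 to 34.7). Respiratory chain genes encoded in the nucleus had a median of -0.12 at percentile 28.6, with 5 of 28 at least 1.5-fold lower and 0 higher.

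DNA repair lists lay inside the range of random lists. Homologous recombination and Fanconi genes had a median of -0.06 at percentile 42.7, with 1 of 25 at least 1.5-fold higher and 2 lower. End joining and damage signalling genes had a median of -0.06 at percentile 38.8, with 1 of 25 higher and 1 lower by 1.5-fold, the lower one being the histone gene H2AFX (1.86-fold, 1.75 to 1.98). Apoptosis regulators had 5 of 29 at least 1.5-fold higher and 7 lower, with a median of -0.01 at percentile 55.8. BCL2A1 rose from 12 to 116 counts, 8.67-fold (4.78 to 17.3), and BMF, which opposes survival factors of the same family, rose 3.92-fold (2.90 to 5.37), while the survival gene BCL2L1 was 1.76-fold lower (1.67 to 1.86). Cytosolic ribosomal proteins had a median of 0.10 at percentile 97.6, barely outside the random range, and this did not hold with the 100-count minimum (percentile 96.8).

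Markers of other cell types and of RNA quality were measured to set beside these groups. Replication-dependent histones had a median of -0.01 at percentile 47.1 over 8 genes, and the mitochondrially encoded transcripts were not analysed here. Luminal breast markers had 4 of 11 at least 1.5-fold higher and 4 lower, with a median of -0.19 at percentile 15.1, and -0.38 at percentile 1.12 without X-linked genes. Basal markers had a median of -0.36 over 6 genes at percentile 6.51, and -0.69 at percentile 0.45 without the most changed gene. Fibroblast and pericyte markers had a median of 0.21 over 5 genes at percentile 53.2, and THY1 was higher with 2 and 47 counts, a ratio of 21.1 (5.52 to 179). Endothelial markers had a median of 0.47 over 5 genes at percentile 93.4 and a mean of 1.15 at percentile 97.6, with TIE1 at 0 and 48 counts, at least 14.3-fold higher, and PECAM1 4.97-fold lower (3.65 to 6.90). Of the blood cell markers, 2 passed the count minimum, too few for a median. The 14 measured markers of the MDA-MB-231 line itself had a median of 0.073 at percentile 87.0, and VIM, the mesenchymal filament vimentin, had a ratio of 1.76 (1.70 to 1.82).

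**Figure D3:**
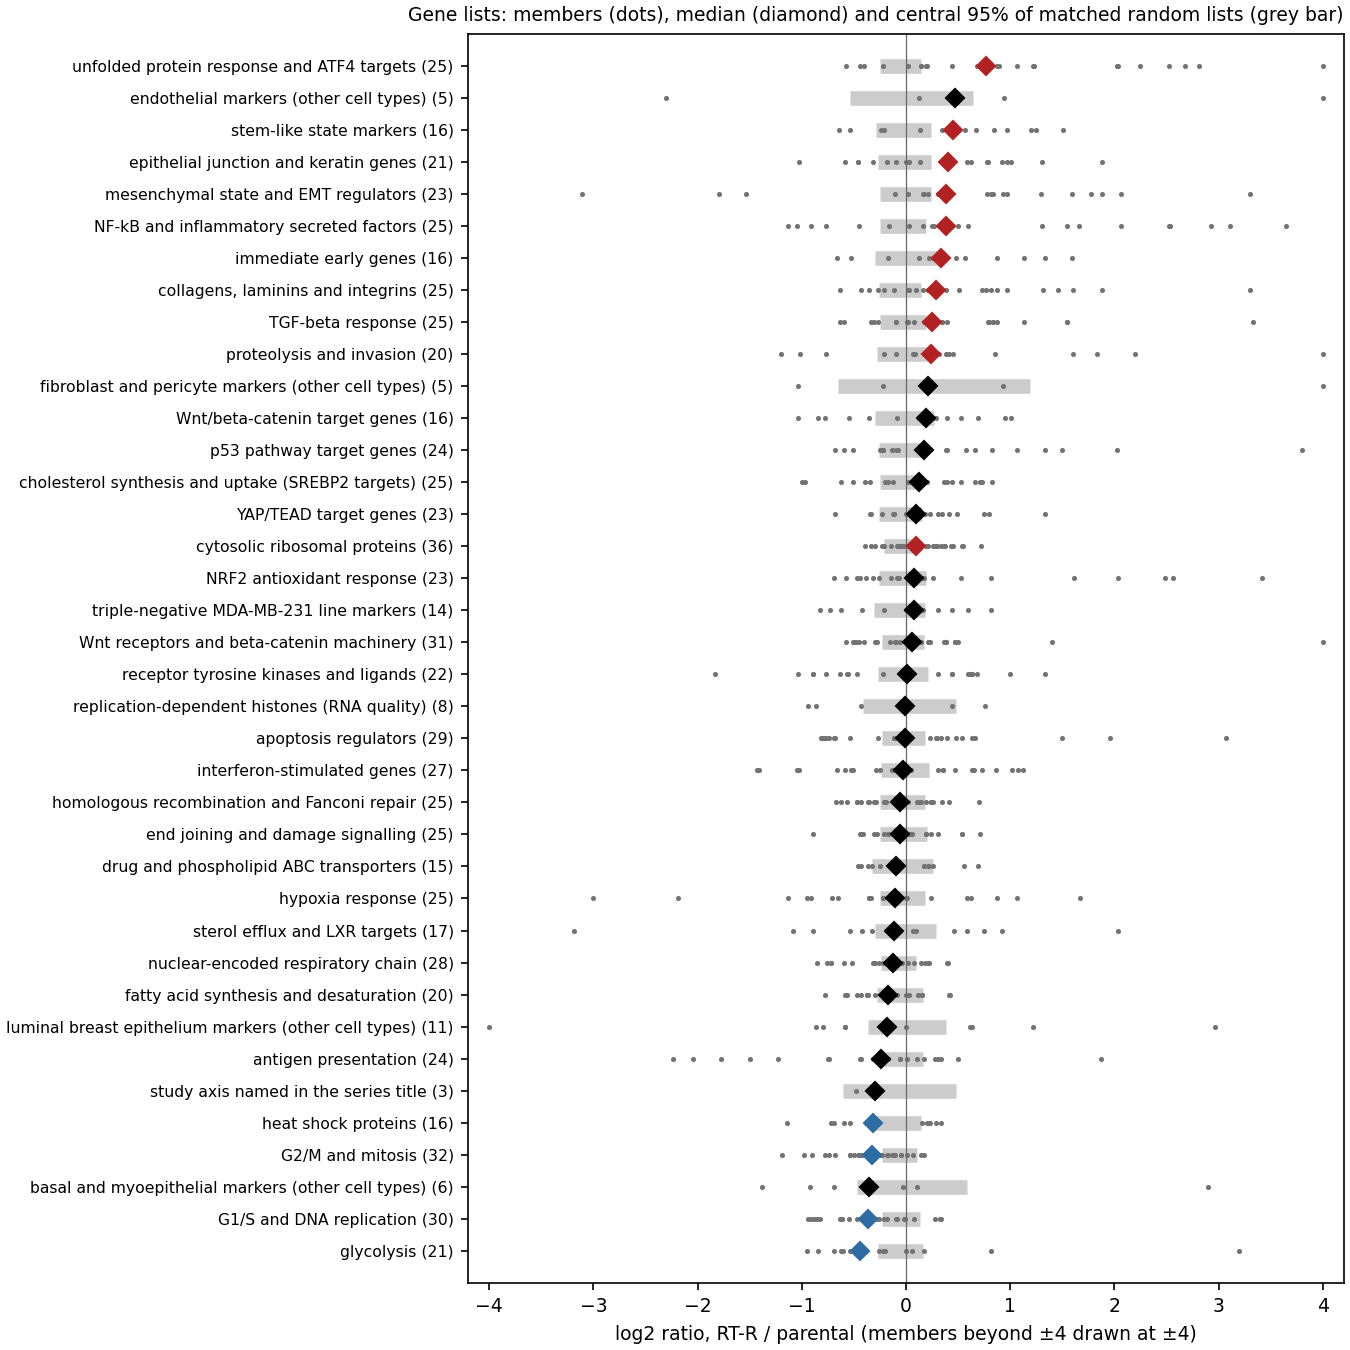
Median log2 ratio of RT-R to parental expression (diamonds, x axis) for the 38 gene lists with at least 3 measured members (y axis, number measured in brackets), with dots for single members, drawn at 4 or -4 when beyond, and grey bars for the central 95% of matched random lists. Red diamonds mark the 10 lists above their random range, led by the ATF4 and unfolded protein response list at 0.77, and blue diamonds the 4 below, led by glycolysis at -0.44.

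Expression also differed by chromosome. The 424 measured X-linked genes had a median log2 ratio of -0.78, 1.72-fold lower in RT-R, and 88.4% of them lay below equal expression. Of all 502 lower genes, 128 (25.5%) were X-linked, although the X carried 3.35% of the genes measured. The 228 genes of chromosome 13 had a median of 0.56, 1.48-fold higher, with 86.4% above equal expression. Chromosome 7 had a median of -0.35 over 601 genes and chromosome 3 one of -0.21 over 711 genes. Along the chromosomes, 36 of 392 windows of about 30 neighbouring genes had a median of at least 0.4 in either direction, against at most 2 in 100 shuffles of the gene order. On chromosome 2, the last 5 windows, from RAPH1 to D2HGDH, had medians between 0.51 and 0.58. On chromosome 3, 5 consecutive windows from DAG1 to IFT57 had medians between -0.88 and -0.43. This comparison was made after the values had been seen.

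**Figure D4:**
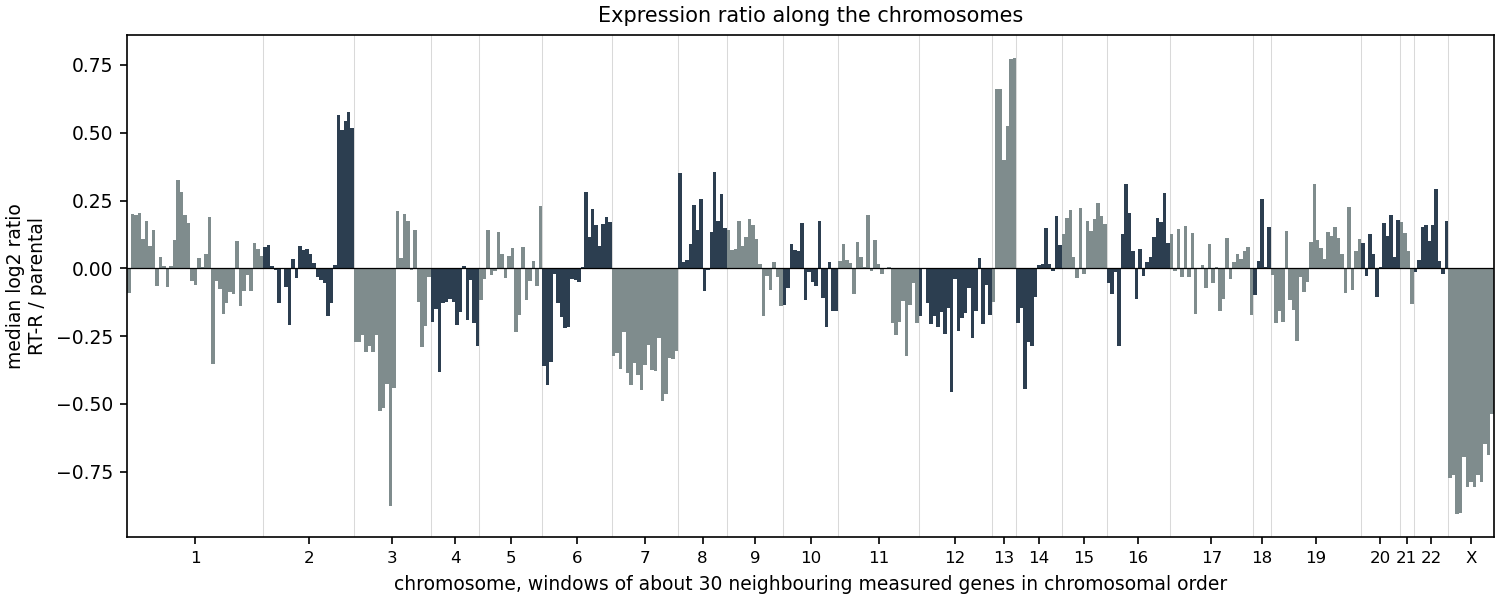
Median log2 ratio of RT-R to parental expression (y axis) in 392 consecutive windows of about 30 measured genes along chromosomes 1 to 22 and X (x axis, gene order), 1 bar per window with alternating shades by chromosome. The X chromosome lies lower throughout (chromosome median -0.78), chromosome 13 higher (0.56) except in its first window (-0.12), the end of chromosome 2 higher (0.51 to 0.58) and part of chromosome 3 lower (-0.88 to -0.43).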

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

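The settings that subtract chromosomal neighbours, leave out X-linked genes or leave out genes identical to an overlapping one were added after the data had been seen, and the others were set beforehand. The count of higher and lower genes depended on the filter and the threshold by construction: 1178 and 657 with no minimum, 356 and 265 with a minimum of 100 counts, 1734 and 1501 at 1.5-fold, and 292 and 67 at 4-fold. Scaling by total counts gave 934 and 442 and a pseudocount of 5 gave 767 and 423. Subtracting neighbours lowered mainly the second count, to 870 and 344 from 871 and 502, as did leaving out X-linked genes (851 and 374). The median absolute log2 ratio, 0.34 as reported, was 0.33 with a pseudocount of 5, 0.47 with no minimum, 0.31 with a minimum of 100, 0.30 after subtracting neighbours and 0.33 without X-linked genes. Of the 14 lists that stood apart, 7 did so under all 12 list settings. The epithelial median changed sign to -0.050 with a minimum of 100 counts, and its mean, 0.32, was inside the random range. Also inside it were the means of glycolysis (-0.18), heat shock (-0.24) and immediate early genes (0.41), and the last 2 without their most changed member (-0.31 and 0.32). Ribosomal proteins lay inside it with a minimum of 100 counts, 20 bins or no X-linked genes (0.0995 each), without the most changed member (0.0876) and after subtracting neighbours (0.0782). Subtracting neighbours also put proteolysis (0.16) and the TGF-beta response (0.20) inside the range and moved CTNNB1 to -0.0028, LRP6 to -0.12, the Wnt target median to 0.015 and the antigen presentation median to -0.062. Other lists left the range: cholesterol synthesis (0.17), p53 targets (0.22) and YAP/TEAD targets (0.24) after subtracting neighbours, luminal markers (-0.38) and antigen presentation (-0.24) without X-linked genes, p53 targets (0.19) with a minimum of 100 counts, receptor tyrosine kinases (0.31) with no minimum, and basal markers (-0.69) without the most changed member. So did the means of p53 targets (0.42), NRF2 targets (0.47), antigen presentation (-0.37), hypoxia (-0.25) and endothelial markers (1.15), the last of which includes a gene with 0 parental counts and so depends on the pseudocount. Where not given by the construction of a setting, the cause was not tested. None of the 227 values of the 30 named genes and of LRP6, LRP5 and CTNNB1 under these alternatives changed sign. The 30 genes were picked for their large differences, so their signs could hardly have changed. The median absolute log2 ratio was 0.63 in the lowest of 5 expression groups and 0.26 in the highest, against 0.24 and 0.03 from counting error alone.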

Other observations

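The gene families, the chromosome comparisons and the tests of explanations in this part were chosen after the values had been seen. Of 16 measured amino acid transporters 7 rose, including SLC7A11 of that list, with a median log2 ratio of 0.49 at percentile 99.97, among them SLC7A5 (1500 and 4623 counts) and SLC3A2 (603 and 2149 counts), the chains of a large neutral amino acid transporter. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had a median of 0.48 over 20 genes, above all random lists, although 7 of them lay below equal expression and only 7 were at least 1.5-fold higher, while the mitochondrial ones had a median of 0.08 over 17 genes at percentile 65.7. Host genes of small nucleolar RNAs had a median of 0.41 over 20 genes, with 7 at least 1.5-fold higher and 2 lower. Of them 2 rose, ZFAS1 (1920 and 6772 counts, log2 ratio 1.66) and GAS5 (880 and 2124 counts, 1.11), and 1 fell, SNHG9 (416 and 226 counts, -1.04). The named members were chosen after their values were seen.

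MHC class II and S100A genes were lower in RT-R. Of 12 measured genes of the class II system, 10 fell, with a median log2 ratio of -1.68, including CD74, the invariant chain (1963 and 774 counts), and HLA-DRA (879 and 417 counts). Of 9 S100A genes, which lie together on chromosome 1, 4 fell and the median was -0.83. S100A6, the most abundant of them, had 122528 and 77083 counts. Of 80 MAGE and related cancer-testis genes found, only 8 passed the count minimum. Of these 8, 5 rose and 2 fell although these genes lie on the X chromosome. Among those that rose were MAGEA3 (9 and 222 counts) and MAGEA6 (11 and 182 counts), near-identical genes whose reads cannot be divided with certainty. The 5 that rose had 1 to 11 parental counts and passed the minimum through the RT-R library alone. PAGE5, which fell, passed it through the parental library alone (48 and 0 counts). The share that rose therefore does not describe the family as a whole. The genes named here were also chosen after their values were seen.

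X-linked genes were lower along the whole chromosome in RT-R, and chromosome 13 genes higher in all windows but the first, whose median was -0.12. A bias by GC content or transcript length is argued against, because the X-linked median was still -0.76 after regression on both. A small number of strongly lower genes could not by itself have set a median. The 88.4% of X-linked genes below equal expression therefore describes how broad the shift was and is not a separate test. A candidate explanation is fewer X copies per RT-R cell, and the pseudoautosomal genes, which lie on the X too, had a median of -0.78 (bootstrap interval -1.01 to -0.43, 13 genes). DNA copy number was not measured here, and lower transcription of the X as a whole stays open. Whether irradiation or drift during culture and subcloning gave rise to it cannot be told apart with 1 library per line.

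The ATF4 targets rose far more than the rest of their list, with a median log2 ratio of 2.03 over 11 genes, all at least 1.5-fold higher. Chromosome-scale shifts and GC or length bias are argued against as the whole cause, because the median was 2.22 after subtracting neighbours and 2.00 after the regression. Whether the endoplasmic reticulum members of the list responded equally cannot be decided here, because the split was made after the values were seen. Those 14 genes had a median of 0.17, with 4 at least 1.5-fold higher. Their bootstrap interval was -0.13 to 0.56, against 1.06 to 2.68 for the ATF4 targets, a description of the 2 parts and not a test of the split. These intervals come from resampling genes and do not cover variation between cultures. As a hypothesis, an amino acid response through ATF4 may be active in RT-R cells but was not tested here. ATF4 protein measured in cultures of equal density and fresh medium would show whether ATF4 is raised, but not what raised it. Culture density or the age of the medium at harvest, which could induce the same genes, is not given in the sources used here.

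There were 9 genes with at most 3 counts in the parental library and at least 100 in RT-R, including ESM1, THBS2, MAGEB2 and PHGDH, and 0 of the reverse kind. RNA from fibroblasts in the RT-R library is argued against, because COL1A2, COL3A1, DCN and LUM, abundant in fibroblasts, had 2, 0, 0 and 2 counts there, and the highest upper counting bound of all the fibroblast and pericyte markers, 9.36 CPM for COL1A1, lay under the 10.2 CPM of PLCB4, the scarcest of the 9 genes. THY1 of the same markers went the other way, from 2 to 47 counts. Another cell line in place of MDA-MB-231 cannot be told apart from a changed derivative, because the line markers had a median log2 ratio of 0.073 and related lines can share such markers. A gain of expression in the derivative itself, or the outgrowth of a minor subclone, stays open and was not tested.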
